A study of Mus musculus with 2 samples.

How the data were processed

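Expression was measured in B cells sorted from a tumour-draining lymph node and from a normal lymph node of Balb/c mice, with 1 array per group. How many animals gave each sample is not given in the sources used here. Per the labels' protocols, 100 ng of total RNA was amplified to biotin-tagged cRNA, fragmented and hybridised to an Affymetrix mouse array. The extraction text attached to both samples speaks of a patient's brain cortex, which disagrees with the tissue, strain and sort given in every other label, and a list of brain cell markers was therefore examined.

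The deposited table held 1 signal intensity per probe set and array on a linear scale, as its values show, with a minimum of 1 reached by 12 probe sets on the draining node array and 16 on the normal node array. MAS5 and RMA are both named, per the submitters' processing notes, with no version and without saying which of them made the table, so the summarisation and background correction behind each deposited intensity are unknown here. The deposited values of both arrays were on a common scale, with mean signals of 379 and 381. No detection calls and no scanner data were used here.

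Probe sets were named from the platform annotation. Of 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 had none. Symbols were checked by gene identifier against a RefSeq gene table of assembly GRCm38.p6, which matched 34741 of the 34945 and replaced 0. No genome build is tied to the array, so no coordinates are given. Probe sets with several symbols or none entered no gene value. Each of the 18193 genes was represented by its probe set with the highest mean over both arrays, and 9010 genes had more than 1 probe set.

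Signals were taken to log2 with no pseudocount and no further normalization. The floor was the median (percentile 50) of all probe sets on each array, 72.4 and 74.9, and a lower value was set to it. A gene above the floor on 1 array only has a bound, its bright signal over the floor of the other array, and bounds enter list medians as such. The median of all probe set differences was -0.04. Because there was 1 array per group, no test was run. Genes were counted by a 2-fold threshold, and list members by a 1.5-fold one. The precision of a single difference is limited by the number of arrays.

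All of these rules, the 39 gene lists and the rule for named genes were fixed before the data were examined. Named genes are the 12 with the largest difference in each direction among genes on both arrays whose probe sets all differed in the same direction, the 5 largest bounds in each direction, up to 4 members per list with the largest absolute difference, members needed to state a count of 5 or fewer, and the genes of the sort. Genes with a provisional symbol were counted but not named. Further list members are named where they bear on the list's name, and these were chosen after their values were seen. For each list with 3 or more measured members, the median difference was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. This percentile describes these 2 arrays and is no p-value. Of 38 lists, about 1 in 20 would lie outside the central 95% if genes varied independently, and 14 lay there. Members of a list can vary together and some stand on several lists, so that share is no measure of chance for the 14. The list step was tested on differences drawn at random and independently for 11395 genes, where 4 of 38 lists lay outside. After 0.5 was added to the cholesterol synthesis genes in a copy of those draws, that list reached percentile 100. The draws had the same spread at every signal level, so they did not test the matching on signal. Fewer than 10000 random lists were used there. The gene counts were tested apart, on simulated arrays of 18193 genes with 200 changed.

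The alternatives were centring, quantile normalization and loess between the arrays, floors at percentiles 40 and 60 and no floor, a pseudocount of 16, the mean over a gene's probe sets, leaving out probe sets of less specific design, thresholds of 1.5-fold and 3-fold, lists without shared members, and random lists without matching. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.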

Results

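The question was which genes differ in expression between B cells of tumour-draining and normal lymph nodes. The data compared sorted B cells from the lymph node that drains a tumour with B cells from a normal lymph node of Balb/c mice, an inbred mouse strain. The tumour was made by injecting 4T1 cells, a mouse mammary carcinoma line of Balb/c origin, under the skin, and the draining node was taken 2 weeks later. Cells that carried CD19, a B cell surface protein, and lacked CD3, the T cell receptor complex, were sorted to a stated purity above 95%. RNA of each sample was read on 1 Affymetrix mouse expression array, so the series held 1 array per group and 2 arrays in all. The difference between them had no replicate check, and no p-value is given for any gene. Each value is the signal of a probe set, a group of short probes against the same transcript. The table held 45037 probe sets with signals from 1 to 21240 on the draining node array and from 1 to 20749 on the normal node array. The median signals were 72.4 and 74.9, and these medians served as the floor below which a signal counted only as a bound. Of 18193 genes with a probe set of their own, 10593 lay at or above the floor on both arrays, 456 on the draining node array only and 346 on the normal node array only. All differences below are log2 draining minus normal. Where a gene had several probe sets above the floor, the SD between them is given, which is a technical spread and no replicate error. Its median over 4868 such genes was 0.14.

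The draining node array differed from the normal node array mainly through genes with higher signal. Among genes on both arrays, 104 were at least 2-fold higher in draining node B cells and 21 were at least 2-fold lower. A further 52 genes above the floor on the draining node array only were higher by at least 2-fold against that floor, against 2 genes in the other direction. Of neutrophil genes, markers of cells outside the sort gate, S100a8 and S100a9 were higher on the draining node array by at least 1.72 and 0.72 and Ltf by 0.37, whereas Mmp9, Ngp, Camp and Cxcr2 stood between -0.0057 and -0.34 and Csf3r was below the floor on both arrays. The central 95% of the 10593 differences ran from -0.52 to 0.64, and log2 signals of the 2 arrays correlated across genes with a Pearson r of 0.981, a figure over genes and not over replicates. On simulated arrays with the same signal levels, 50 of 50 genes with a true 4-fold change and 22 of 50 with a true 2-fold change passed the 2-fold threshold, and 3 of 10449 unchanged genes did. The simulated noise was normal, with a spread taken from the differences between these 2 arrays at each signal level. It held no separate variation between animals or sorts, so 3 of 10449 is no false positive rate for the counted genes.

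**Figure D1:**
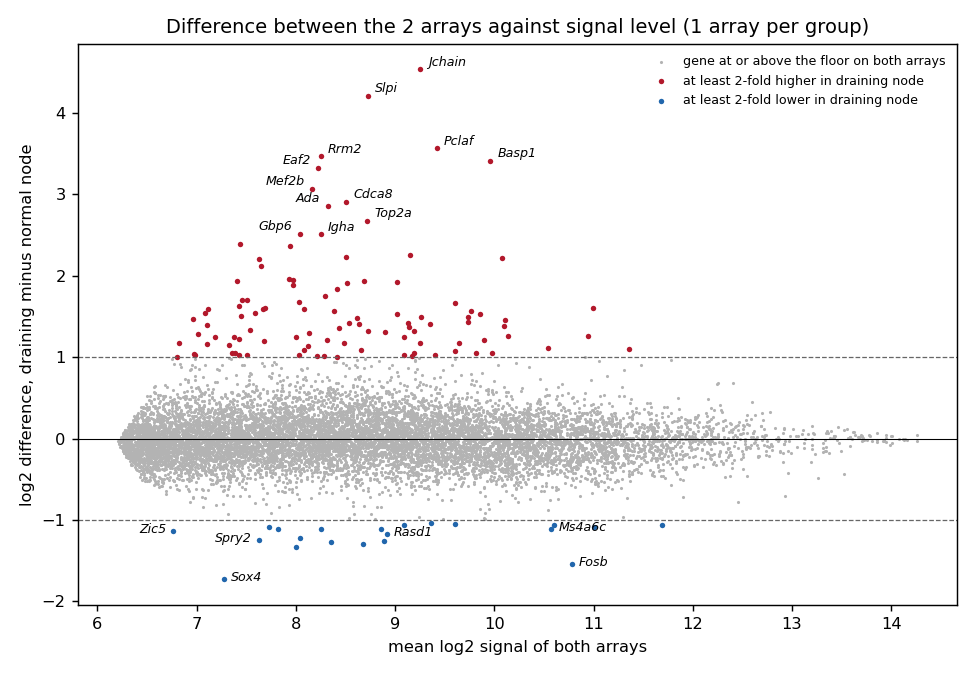
Log2 difference (draining minus normal node) against the mean log2 signal of both arrays, with 1 point per gene at or above the floor on both arrays and dashed lines at 2-fold. The 104 genes at least 2-fold higher reach up to 4.53 for Jchain, whereas the 21 genes at least 2-fold lower reach down to -1.73 for Sox4.

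Of the 12 genes with the largest positive differences, Jchain, the joining chain of secreted IgM and IgA, was 23.2-fold higher, with signals of 2943 and 127. Slpi, a secreted protease inhibitor, was 18.5-fold higher, and Basp1, a membrane-associated protein on the germinal centre list, 10.6-fold higher. Pclaf, a partner of the replication clamp PCNA, was 11.8-fold higher, and Rrm2, a subunit of ribonucleotide reductase, differed by 3.47 with an SD of 1.01 over 3 probe sets. Eaf2, a transcription elongation factor, differed by 3.33. Mef2b, a transcription factor of germinal centre B cells, was 8.38-fold higher, and Ada, adenosine deaminase, 7.27-fold. Cdca8, a part of the chromosomal passenger complex, differed by 2.91 with an SD of 0.83 over 3 probe sets, and Top2a, topoisomerase II alpha, by 2.67 with an SD of 1.56 over 2 probe sets. Gbp6, an interferon-induced guanylate-binding protein, differed by 2.51 with an SD of 0.13 over 2 probe sets. Igha, the IgA heavy chain constant region, differed by 2.51 with an SD of 0.39 over 3 probe sets.

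The 12 genes with the largest negative differences differed by smaller factors. Sox4, a transcription factor of early lymphocyte development, was 3.31-fold lower, with a difference of -1.73 and an SD of 0.66 over 3 probe sets, and Fosb, an AP-1 subunit, was 2.91-fold lower. Ahnak, Pgap1, Frat2, Spry2, Tifa, Rasd1 and Zic5 lay between -1.33 and -1.14, each on 1 probe set above the floor. Zic5 read 73.29 on the draining node array, close to the floor. With the 60th percentile floor it stood at -0.58, short of 1.5-fold. St8sia6, a sialyltransferase, differed by -1.11 with an SD of 0.12 over 3 probe sets, Rsf1, a chromatin remodelling factor, by -1.11 with an SD of 0.22 over 3 probe sets, and Ms4a6c by -1.11 with an SD of 0.75 over 2 probe sets. Under the mean over probe sets Ms4a6c stood at -0.58, short of 1.5-fold. Of genes below the floor on the draining node array, Asb10 was at least 2.01-fold lower and Lef1, a transcription factor of T cells and early B cells, at least 1.89-fold lower. Afm, Ovgp1 and Foxf1 had bounds of 1.75-fold, 1.64-fold and 1.61-fold. A bound shrinks as the floor rises, and with the floor at the 60th percentile these 5 lay between -0.43 for Asb10 and -0.12 for Foxf1, short of 1.5-fold.

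Genes of the germinal centre, the site where activated B cells divide and mutate their antibody genes, were higher in draining node B cells. Of 16 measured members of the list, 12 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. The list median of 1.20 exceeded the medians of all 10000 random lists matched on signal level. Besides Basp1 at 3.41 and Mef2b at 3.07, Rgs13, a regulator of G protein signalling, was higher by at least 3.08 on the log2 scale, with a signal of 633 against one below the floor. S1pr2, the receptor that holds B cells in the germinal centre, differed by 2.21 with an SD of 0.30 over 2 probe sets. Bcl6, the transcription factor that directs the germinal centre programme, went the other way, at -0.42 with an SD of 0.060 over 2 probe sets, and so did Lmo2 at -0.20. Gna13 read -0.11 with an SD of 0.17 over 7 probe sets, which differed in sign. Aicda, the antibody-mutating deaminase, had no probe set named for it alone and is not analysed here.

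Cell cycle genes were also higher in draining node B cells. Of 33 measured members, 26 were at least 1.5-fold higher and 0 were at least 1.5-fold lower, with 19 at least 2-fold higher, bounds included. The list median was 1.13, again above all 10000 random lists. Most of the 19 were below the floor in normal node B cells, so their differences are bounds. The 19 are thus not a share of the 2-fold count of genes on both arrays. Cdk1, the mitotic kinase, was at least 13.2-fold higher, Ccna2, cyclin A2, at least 10.5-fold with an SD of 0.24 over 2 probe sets, Ccnb2, cyclin B2, at least 9.62-fold, Birc5, survivin, at least 9.26-fold, and Ube2c, a ubiquitin-conjugating enzyme of mitosis that stood outside the list, at least 9.23-fold. Mcm6, a replication licensing factor, differed by 1.53 with an SD of 0.36 over 3 probe sets. The 3 members with a negative value had probe sets that disagreed in sign, namely E2f1 at -0.42 with an SD of 0.63 over 3, Cdc45 at -0.25 with an SD of 1.26 over 2 and Foxm1 at -0.18 with an SD of 0.14 over 2. Genes of ribosome biogenesis and Myc targets had a median of 0.053, at the 87.0th percentile of random lists, and Myc itself differed by -0.42.

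Signals under the names of the heavy chain genes Igha and Ighg3 were higher, as were the joining chain gene Jchain and part of the plasma cell list. No light chain probe set reached 2-fold. Among 15 measured plasma cell genes 5 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. The median was 0.31, at percentile 99.99 of random lists. Jchain and Eaf2 led the list, followed by Xbp1, a transcription factor of secretory cells, with signals of 2724 and 1363 and an SD of 0.40 over 4 probe sets. Derl3 and Creld2, endoplasmic reticulum proteins, stood at no less than 0.97 and at 0.67, the former at 0.43 with the 60th percentile floor. The plasma cell regulator Irf4 differed by -0.45 with an SD of 0.24 over 2 probe sets, and the surface proteoglycan Sdc1 by -0.47 with an SD of 0.25 over 4 probe sets, which differed in sign. Prdm1 and Tnfrsf17 were below the floor on both arrays. Of the 12 constant region genes listed, 3 had a probe set of their own, with Igha at 2.51, Ighg3 at 1.93 with an SD of 0.33 over 2 probe sets, and Ighm at -0.16, and their median of 1.93 exceeded all random lists. The probe sets named for Ighm disagreed. Of 8 above the floor, 5 were at least 2-fold higher, 3 lay within 1.5-fold, and the SD between them was 2.74. The brightest read 9786 and 10913, whereas another read 5312 and 101. These probe sets were singled out after their values were seen. Constant regions are similar in sequence and the probe names come from an older annotation, so these probe sets cannot be assigned to one isotype here. The same doubt holds for the probe sets named for Igha and Ighg3. Of 41 immunoglobulin and joining chain probe sets above the floor, those shared by several segments included, 12 were at least 2-fold higher and 0 at least 2-fold lower. All 12 were heavy chain or joining chain probe sets. The 24 kappa and lambda light chain probe sets had differences from -0.48 to 0.67, with a median of 0.089. Genes of the unfolded protein response had a median of 0.28, above all random lists, with 3 of 21 at least 1.5-fold higher, namely Sdf2l1 at 1.25, Xbp1 and Creld2, and 1 at least 1.5-fold lower, Dnajb9 at -0.74. Xbp1, Creld2, Edem1, Calr and Pdia3 also stand on the plasma cell or MHC class I list, and without them the median was 0.16. Under the mean over probe sets it was 0.18, and both values stayed above the central 95% of random lists.

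**Figure D2:**
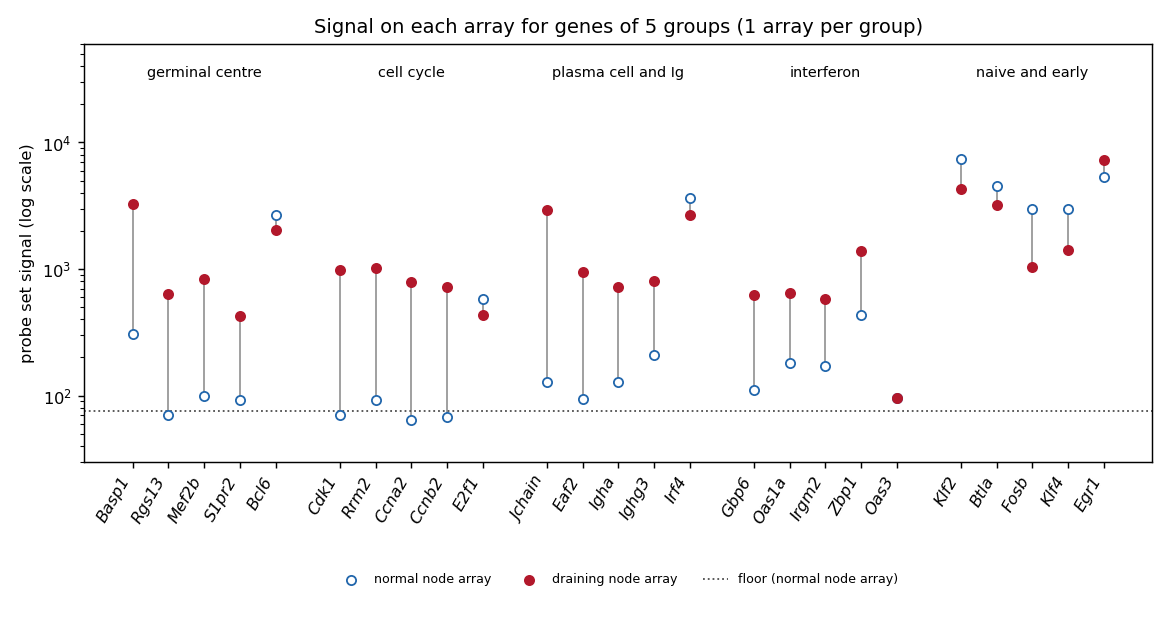
Probe set signal on a log axis for 25 genes in 5 groups, with an open circle for the normal node array, a filled circle for the draining node array and a dotted line at the floor of the normal node array. Cdk1 read 989.8 against 70.1 and Jchain 2943 against 127, whereas the plotted probe sets of Bcl6, E2f1 and Irf4 were lower in the draining node, E2f1 with other probe sets of opposite sign, and the 2 points of Oas3 coincide at about 96.

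Interferon-responsive genes were higher in draining node B cells. Of 22 measured interferon-stimulated genes, 14 were at least 1.5-fold higher and 0 were at least 1.5-fold lower, with a median of 0.90. Of 16 measured genes on the list named for interferon gamma, 11 were at least 1.5-fold higher and 0 lower by that factor, with a median of 1.002. Both medians exceeded all random lists, and whether an interferon acted, or which, was not tested. Oas1a, an antiviral nucleotide synthetase, differed by 1.84, Zbp1, a nucleic acid sensor, by 1.67 with an SD of 0.025 over 2 probe sets, Usp18, which trims ISG15 from proteins, by 1.59 and Rtp4 by 1.53 with an SD of 0.91 over 2 probe sets. In the second list Gbp6 was followed by the immunity-related GTPases Irgm2 at 1.75, Irgm1 at 1.43 and Iigp1, at least 2.83-fold higher with an SD of 0.72 over 2 probe sets, or by 0.96 on the log2 scale with the 60th percentile floor. The 1 member of each list with a negative value was Oas3, at signals of 96.29 and 96.31, and Cxcl9 at -0.22. Genes of MHC class I presentation had a median of 0.32, above all random lists, and all 13 were positive. Nlrc5, the transactivator of class I genes, differed by 1.49, the immunoproteasome subunits Psmb9 and Psmb8 by 1.10 and 0.50, and the peptide transporter gene Tap1 by 0.74. Nlrc5, Psmb9 and Tap1 were the 3 past 1.5-fold, and Psmb9, Tap1 and Psmb8 also stand on the interferon gamma list. MHC class II genes had a median of 0.028, at the 82.2nd percentile, with H2-Oa the most different at 0.29.

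All 15 measured cholesterol synthesis genes were positive, 7 of them by at least 1.5-fold, and the median of 0.48 exceeded all random lists. Msmo1, Fdps, Cyp51 and Idi1 stood at 0.91, 0.91, 0.91 and 0.88, with an SD of 0.37 over 2 probe sets for Cyp51. The oxidative phosphorylation median of 0.18 also exceeded all random lists, although 0 of 23 genes reached 1.5-fold. Cycs at 0.32 with an SD of 0.083 over 3 probe sets and Ndufa9 at 0.31 were the most different. The glycolysis and hypoxia median of 0.13 lay at the 98.2nd percentile, with 2 of 17 genes at least 1.5-fold higher, Tpi1 at 0.89 with an SD of 0.092 over 3 probe sets and Pkm at 0.63. That list left the outer range under 4 alternatives, with percentiles of 91.1 to 97.1.

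Genes of resting follicular B cells were lower in the draining node. The median of 11 measured genes was -0.29, at percentile 0.06 of random lists, and 9 of 11 were negative. Klf2, a transcription factor of quiescence and recirculation, was 1.72-fold lower at -0.78 and was the only member past 1.5-fold. Btla, an inhibitory receptor, differed by -0.51, Foxp1 by -0.43 with an SD of 0.079 over 8 probe sets, and Cd55 by -0.30 with an SD of 0.17 over 3 probe sets. Immediate early genes, which respond within minutes to stimulation and also to cell handling, had a median of -0.18 at percentile 0.18. Of 22 genes 6 were at least 1.5-fold lower, namely Fosb at -1.54, Klf4 at -1.08 with an SD of 0.090 over 2 probe sets, Jun at -0.72 with 0.065 over 2, Dusp1 at -0.71, Klf6 at -0.62 with 0.079 over 4 and Nr4a2 at -0.61 with 0.26 over 5. Rgs1 at 0.85 was the only one at least 1.5-fold higher, and Egr1 stood at 0.45. The heat shock and stress list had a median of -0.045, at the 35.4th percentile, with Bag3 at -0.68 its 1 member past 1.5-fold. With the 60th percentile floor Bag3 stood at -0.28. NF-kB target genes had a median of -0.071, at the 19.3rd percentile, with Cd83 at 0.68, Traf1 at 0.61 with an SD of 0.36 over 2 probe sets and Icam1 at 0.59 past 1.5-fold on one side and Tnfaip3 at -0.72 with an SD of 0.067 over 2 probe sets on the other. This list's median was -0.17 at percentile 1.17 with the floor at the 60th percentile, and -0.32 at percentile 0.03 over the 12 members held by no other list.

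**Figure D3:**
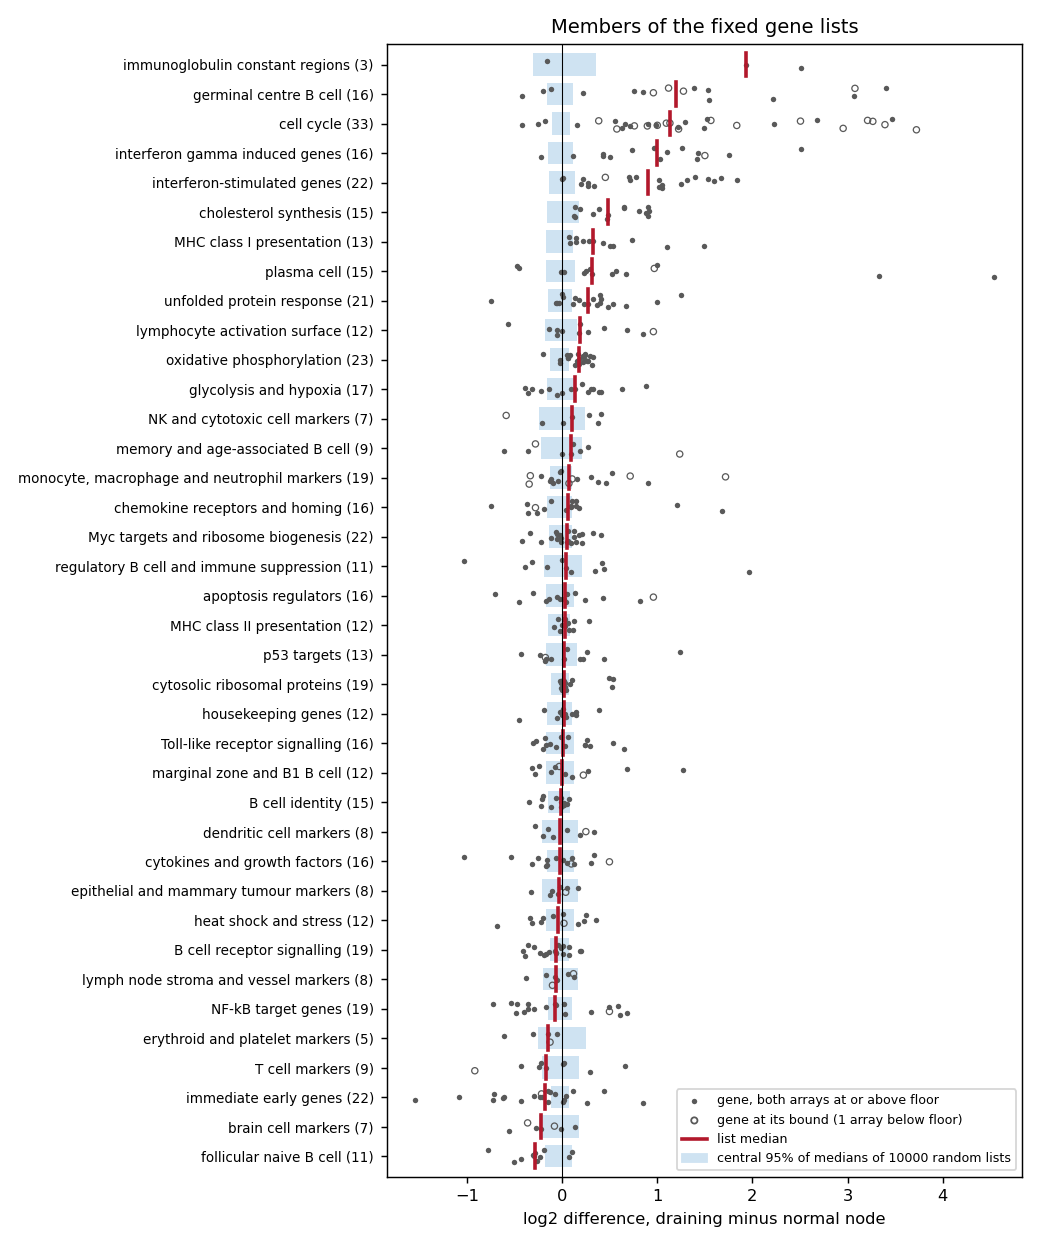
Log2 difference (draining minus normal node) of each measured member of 38 gene lists fixed beforehand, with the number of members in brackets, filled points for genes on both arrays, open points for bounds, a red bar at the list median and a blue band for the central 95% of medians of 10000 random lists. Medians of 12 lists lie above the band and those of 2 lists, follicular naive B cell and immediate early genes, below it.

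Surface activation genes had a median of 0.18, at the 98.8th percentile, with 3 of 12 at least 1.5-fold higher. These were the death receptor gene Fas at no less than 0.96, or 0.42 with the 60th percentile floor, the costimulatory ligand gene Cd86 at 0.85 with an SD of 0.33 over 2 probe sets and Cd83 at 0.68, while Cd69 stood at -0.57. All 3 also stand on other lists, and the 6 members held by no other list had a median of -0.049. Among chemokine receptor and homing genes, whose median of 0.068 lay at the 91.3rd percentile, S1pr3 differed by 1.68 with an SD of 0.75 over 2 probe sets, Cxcr3, the receptor for interferon-induced chemokines, by 1.20 and the integrin gene Itga4 by -0.75 with an SD of 0.45 over 4 probe sets. Genes tied to regulatory B cells and immune suppression had a median of 0.045, at the 66.5th percentile, and of 0.34 at the 98.5th percentile over the 5 members held by no other list. Havcr1, which encodes TIM-1, differed by 1.96 with an SD of 1.23 over 2 probe sets, Cd274, which encodes PD-L1, by 0.45, and Il12a by -1.03. Il10 was below the floor on both arrays. Of 27 cytokine and growth factor genes 11 were below the floor on both arrays, and the median of the other 16 was -0.025, with Il12a the 1 gene past 1.5-fold, Tnf at no less than 0.50 and Ccl4 at -0.53. With the 60th percentile floor Tnf had no bound, since both signals lay below that floor.

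Lists that bore on other B cell states lay inside the central 95% of random lists. B cell identity genes had a median of -0.014, with Ms4a1, which encodes CD20, at -0.015 with an SD of 0.12 over 2 probe sets, Cd79b at 0.011 and Ebf1 at -0.34 with an SD of 0.080 over 4 probe sets. The marginal zone and B1 list had a median of 0.00071 with Dtx1 at 1.27 and an SD of 0.94 over 2 probe sets, which differed in sign, and Plac8 at 0.68. The memory and age-associated list had a median of 0.090 with Tbx21, which encodes T-bet, at no less than 1.24, or 0.69 with the 60th percentile floor, and Zeb2 at -0.61 with an SD of 0.31 over 4 probe sets. B cell receptor signalling genes stood at a median of -0.062 and Toll-like receptor genes at 0.0098, with the adaptor gene Ticam1 at 0.65. Apoptosis regulators had a median of 0.031, with Bid at 0.82 and an SD of 0.073 over 2 probe sets, and Bcl2 at -0.70 and an SD of 0.15 over 5. The p53 targets had a median of 0.026, with Cdkn1a at 1.24 and an SD of 0.52 over 2 probe sets. Cytosolic ribosomal proteins had a median of 0.025 and housekeeping genes of 0.020.

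Markers of cells that the sort should have removed were measured alongside. Of 19 T cell genes 10 were below the floor on both arrays, including Cd3d and Cd3g. The other 9 had a median of -0.17, with Cd8a at 0.66 and an SD of 0.49 over 2 probe sets, which differed in sign, and Cd3e at -0.43 with signals of 602 and 809. With the floor at the 60th percentile 7 T cell genes had a median of -0.23, at percentile 1.27. Cd19 had no probe set named for it alone and is not analysed here. Myeloid genes had a median of 0.073, at the 93.4th percentile, and 3 of 19 were at least 1.5-fold higher. These were the neutrophil calprotectin genes S100a8 at no less than 1.72 and S100a9 at no less than 0.72, and Mpeg1 at 0.90. With the 60th percentile floor the bounds of S100a8 and S100a9 were 1.17 and 0.17, the second short of 1.5-fold. Lyz2 differed by 0.52. Under the mean over probe sets this list's median was 0.16, at the 99.8th percentile. Klrk1, the 1 NK and cytotoxic gene past 1.5-fold, had a bound of -0.59 that the 60th percentile floor ended. NK and cytotoxic genes had a median of 0.11, stroma and vessel genes of -0.063, erythroid and platelet genes of -0.14, and epithelial and mammary tumour genes of -0.030, all inside the central 95%. Dendritic cell genes had a median of -0.020 and a mean of 0.013, which differ in sign. Of 17 brain cell genes, included because one label text names brain tissue, 10 were below the floor on both arrays, and the other 7 had a median of -0.22 at the 3.75th percentile, or the 2.06th under the mean over probe sets, with Mobp at -0.55 and Mbp at signals of 1415 and 1428 with an SD of 0.13 over 4 probe sets. In these mice Xist, the X-inactivation transcript, read 5265 and 6251 with an SD of 0.24 over 3 probe sets, and the Y-linked genes Kdm5d, Eif2s3y and Uty were below the floor on both arrays.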

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

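The tests of the third paragraph were set before their results were seen, and the share of unnamed probe sets that prompted them was seen first. Probe sets without a single gene name entered no gene value of the report, apart from the count of immunoglobulin probe sets, and 5 of them were at least 8-fold higher on the draining node array than on the normal node array, which served as the control.

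The brightest of them was 33.9-fold higher, with signals of 4441 and 131. A probe set shared by the immunoglobulin genes Ighv14-2, Ighg3 and Ighm was at least 28.2-fold higher, with 2116 against a signal below the floor. A pair of others below the floor in the normal node sample were at least 25.9-fold and 22.7-fold higher, with 1940.4 and 1704 in the draining node sample. The last was 18.7-fold higher, with signals of 1528 and 81.6. Of the 5, the shared immunoglobulin probe set is the 1 with gene names here.

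Unnamed probe sets were also frequent at the other end. Among probe sets on both arrays, 13.1% had no gene name, against 5.95% (10 of 168) of those at least 2-fold higher and 30% (18 of 60) of those at least 2-fold lower. Dimmer signal of unnamed probe sets does not account for this, since draws matched on signal level held a median of 6 unnamed probe sets and a central 95% range of 2 to 11, against the 18 observed. A general loss of signal from unspliced or alternatively ended transcripts in the draining node sample was tested in 4464 named genes with several probe sets. For each gene the draining minus normal difference of its brightest probe set was subtracted from that of its dimmest. The median was 0.0087 (95% bootstrap interval 0.0013 to 0.020), with 48.1% of genes negative. The interval is over genes and is no replicate error. This test cannot decide the question, since a dimmest probe set need not read such transcripts and probe sets below the floor on either array were left out. Such a loss stays open, and target positions of the unnamed probe sets were not used here. A difference between the nodes stays open and was not tested.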

How the results depend on the processing

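No paired analysis was possible because each group had 1 array, and for the same reason no replicate could be left out. The count of 104 genes at least 2-fold higher became 238 with no floor, 319 at 1.5-fold and 38 at 3-fold, and the count of 21 lower genes became 70, 159 and 1, as a lower floor admits dim genes and a threshold sets the count directly. Under the other 8 alternatives it ran from 78 to 127 higher and from 17 to 22 lower. Loess, quantile normalization and centring each kept all 104 higher genes. Of the 14 lists outside the central 95% of random lists, 12 stayed outside on the same side under all 11 alternatives. Glycolysis and hypoxia came inside with a median of 0.092 under the 40th percentile floor, no floor and the mean over probe sets, and of 0.13 without shared members. The surface activation list came inside with 0.088 under no floor and turned to -0.049 without members of other lists, where 6 genes remained. The cause was not tested. In 6 cases a list entered the outer range under an alternative, namely NF-kB targets at -0.17 and T cell markers at -0.23 with the 60th percentile floor, myeloid markers at 0.16 and brain cell markers at -0.22 under the mean over probe sets, and NF-kB targets at -0.32 and regulatory genes at 0.34 without members of other lists. Of 1525 values of named genes under alternatives, 97 moved by more than the SD between the gene's probe sets, or the median SD for genes with 1 probe set, and no gene past 1.5-fold changed sign. Bounds shrank with the 60th percentile floor, where those of S100a9, Fas, Derl3, Klrk1, Asb10, Lef1, Afm, Ovgp1 and Foxf1 no longer reached 1.5-fold. Of genes on both arrays, Zic5, Bag3 and Cd8a also fell short of 1.5-fold with that floor, at -0.58, -0.28 and 0.24. Signal over background limits dim genes, for which the deposited table gives no detection call.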

Other observations

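The tests in this part were chosen only after the results they bear on had been seen, and the lists of these first 2 paragraphs were written after the fixed lists had been examined. Of 16 nucleotide synthesis genes 5 were at least 1.5-fold higher and 15 were positive, with a median of 0.34 above all random lists. The 5 were the thymidine kinase gene Tk1 at 1.13, the folate enzyme gene Mthfd2 at 0.86 with an SD of 0.18 over 2 probe sets, Dctpp1, Rrm1 and Dut. All 13 measured genes of mismatch and excision repair were positive, 5 of them by at least 1.5-fold, with a median of 0.41 at percentile 99.99. Of the 13, 2 stood on a fixed list and had been seen. The 5 past 1.5-fold were DNA ligase Lig1 at 1.22, the clamp loader gene Rfc4 at 1.09, the polymerase gene Pole at 0.98, the uracil glycosylase gene Ung at 0.76 and the error-prone polymerase gene Polh at 0.73 with an SD of 0.58 over 4 probe sets of differing sign. All 14 core proteasome genes were positive but none reached 1.5-fold, with a median of 0.25 above all random lists and Psma7 the highest at 0.38.

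Of 11 measured genes of the germinal centre light zone 9 stood on fixed lists, so the median of 0.45 mostly restates values already given. The members not seen before were Ccnd2 at 0.64 with an SD of 0.12 over 7 probe sets, and Batf at 0.35. Of 7 dark zone genes 3 were at least 1.5-fold higher, with a median of 0.068 at the 78.3rd percentile. These 3 were Hmmr at no less than 1.29, Hmgb2 at 1.11 with an SD of 0.12 over 2 probe sets and Polh at 0.73, whereas the homing receptor gene Cxcr4 stood at -0.36 and Foxo1 at -0.32 with an SD of 0.10 over 4 probe sets. Of immature and transitional B cell genes not looked at before, 8 were measured, with a median of -0.11 at the 17.5th percentile, inside the central 95%. The idea, prompted by the lower Sox4, that such genes are lower as a group was thus not borne out on these members.

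The first pattern weighed is the higher signal of cell cycle and germinal centre genes. A signal-dependent difference, shared by genes of like signal, is argued against by the germinal centre median, at 1.20 before loess and 1.28 after. Its percentile could hardly move, since the random lists were already matched on signal level. A larger share of T cells carried through the CD3-negative sort is argued against by a T cell marker median of -0.17. Its SD was 0.44 over 9 genes, of which Bcl11b and Lat lay near the floor, and the cell cycle median was 1.13. Cd3e read 602 and 809, whereas 10 of 19 T cell genes, Cd3d and Cd3g included, were below the floor on both arrays. T cells of equal share in both samples would leave these markers level, so the markers do not bear on them. A larger share of germinal centre B cells among the sorted cells may account for it but stays open. The follicular list, which lies outside the pattern, was lower at -0.29. Among germinal centre genes the dark zone list, at 0.068, lay inside the central 95% of random lists, and Bcl6 read -0.42. Neither decides the question, since the dark zone list held 7 measured genes, of which 3 were at least 1.5-fold higher. Bcl6 was bright on both arrays, at 2017 and 2690, as was the dark zone gene Cxcr4, at 4754 and 6085. With 1 array per group, a difference of animal, sort or array other than the tumour cannot be told apart from the tumour.

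The second pattern is the lower signal of immediate early genes. The median was -0.18 before loess and -0.14 after, which argues against a difference shared by genes of like signal as the whole cause. The percentile after loess was 0.42, but it could hardly move, since the random lists were matched on signal level. Handling stress that differed between the samples could lower these genes. It cannot be told apart from a difference between the nodes with 1 array per group. The heat shock and stress genes, at a median of -0.045, do not decide it, with 6 positive and 6 negative. A biological difference between the nodes stays open and was not tested.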
